A study of Homo sapiens with 10 samples.

How the data were processed

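Small RNA was sequenced from SUM159PT, a triple-negative breast cancer cell line, in 10 libraries. Per the labels, cells received a lentiviral construct in which GFP was joined to part of a 3'UTR that holds a site for a miRNA, and RNA was taken 7 days after infection. Per the submitters' protocol notes, total RNA came from miRNeasy columns and the libraries were made with the Illumina TruSeq small RNA kit. Per the submitters' processing notes, cutadapt 1.9.1 and Bowtie (version not stated) were used. The genome build, the miRNA annotation, the mismatches allowed and the filters are not stated in the sources used here.

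The deposited table holds 1385 mature miRNAs in 10 columns. Its name says TPM, and the values were tested for their unit. In every library 100% of the values were whole multiples of 1 step within a tolerance of 1e-06, with no length term, so the deposited values are RPM: reads of a miRNA as a share of the reads given to all miRNAs listed, scaled to the same total in every library. The steps gave back the reads, which were 3534573 to 5369054 per library. A value carried by 3 reads equals 0.559 to 0.849 RPM, which was taken as the floor of each library. Reads were amplified without molecular identifiers, so intervals and floors cover counting error only. The "hsa-" prefix of the miRNA names was dropped.

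Groups follow the titles: a TRAF6 construct and an ABCA1 construct with 2 libraries each, an HADHB construct with 2 libraries, and a scrambled control with 4 libraries. The labels conflict for the HADHB libraries, whose titles start with HADHB while their free text names the ABCA1 3'UTR. The sample names of the table give HADHB and were followed, so every value for this construct carries that doubt. Control titles carry the numbers 1 and 2 in both control pairs, so the replicate numbers 1 to 4 at their end were used here. Nothing in the labels says whether replicates are separate cultures or infections, so p-values measure only the spread between these samples, which may be technical. No batch or date is given in the labels. Correlations of replicate differences between groups ran from -0.37 to 0.38 (Pearson, across miRNAs, which are not independent), so the numbers were not taken to pair libraries.

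miRNAs at 5 RPM or more in at least 2 libraries were tested, which left 386 miRNAs with 99.95% of the reads (in percent, over all libraries). limma 3.58.1 in R 4.3.3 was run with a mean-variance trend on log2(RPM + 1), 1 mean for each of 4 groups, all 10 libraries in the same model and 6 residual degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over all miRNAs tested and a threshold of 0.05. Fold changes, standard errors (SE) and adjusted p-values are from this model unless another is named. A level given as so many fold lower is the log2 fold change of this model put back on the linear scale. It rests on log2(RPM + 1), so it differs from the ratio of the mean RPM values. The 4 miR-33 and miR-146 guides were also adjusted among themselves, which is called adjusted over the list alone. edgeR 4.0.16 (quasi-likelihood test with TMM on the recovered reads) was run beside it. Exact permutation tests (two-sided) were enumerated for the labelled substrates. They treat single libraries as exchangeable, which the difference between the control pairs given below puts in doubt. With 2 against 4 libraries there are 15 splits and the smallest p is 0.0667. With 4 against 4 there are 70 splits and the smallest p is 0.0286.

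The comparisons, lists, settings and the rule for named miRNAs were fixed before the data were examined. The rule takes the miR-33 and miR-146 guides and passengers in every comparison. It also takes up to 10 miRNAs per direction past the threshold with a mean of at least 10 RPM and every construct library on the same side of every control library. Up to 3 members of each list with the smallest p and the 5 most abundant miRNAs of the controls complete it. The text names the member of each list with the smallest p and says where a miRNA was chosen after its values were seen. miR-33 passengers and miR-146a-3p were not analysed here, and miR-146b-3p was below the filter.

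The 21 lists are the miR-146 guides, miR-146 passengers, miR-33 guides, miR-33 passengers, let-7 family, miR-17-92 cluster and paralogs, miR-200 family, miR-15/16 family, miR-34/449 family, miR-29 family, miR-30 family, miR-181 family, inflammation-induced miRNAs other than miR-146, reported ABCA1-targeting miRNAs other than miR-33, miRNAs with reported endogenous triggers of degradation, the 14q32 cluster, the C19MC cluster, blood cell markers, liver, muscle and neuron markers, mesenchymal and basal breast miRNAs, and hypoxia and stress. The 13 lists that do not hold the substrates and had at least 3 tested members were tested with camera (preset correlation 0.01), with camera and an estimated correlation, and with fry. fry tests whether the members move on balance in 1 direction and does not compare them with other miRNAs. Arm ratios were tested with limma on the log2 ratio of 5p to 3p over 92 hairpins, of which 91 had both arms past the filter and miR-146b was added for its label.

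Hairpin positions and 3'UTRs came from GENCODE release 29 on GRCh38. Matches to bases 2 to 8 of a miRNA were counted in the annotated 3'UTRs of the 3 genes, with mature sequences written from memory and found in their annotated hairpins. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15, numpy 2.4.6).

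The model was tested on simulated data, with a single draw per setting. Each library was drawn on its own around 1 mean per miRNA, with the spread of these libraries. The simulated data hold no difference between control pairs and no shift shared across miRNAs. The numbers below therefore do not cover that part of the real data. With 0 of 386 miRNAs changed, limma and edgeR each called 0 for the ABCA1 and TRAF6 designs. With 20 changed miRNAs in the ABCA1 design, limma called 3 of 6 changed by 4-fold, 1 of 7 changed by 2-fold and 0 of 7 changed by 1.5-fold. In the TRAF6 design it called 4 of 6, 2 of 7 and 0 of 7, and 1 of the 366 unchanged miRNAs, which was 14.3% of its 7 calls. With 200 changed miRNAs limma called 13 of 186 unchanged miRNAs in the ABCA1 design, 9.22% of its 141 calls and above the threshold of 5%, and 3 of 186 in the TRAF6 design, 2.42% of its 124 calls. edgeR called 6 and 3 of the 186.

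Alternatives were pseudocounts of 0.1 and 10, no filter, a filter of 50 RPM, TMM and median-of-ratios rescaling, limma without the trend, edgeR, either pair of control libraries alone, only the compared groups in the model, a term for each of the replicate numbers in the titles, and leaving out each library. Chosen after seeing the data were the control pairs as 2 groups with each contrast against the mean of both, the contrast between the pairs, and leaving out 3 libraries that shared low values of miR-125a-5p and miR-28-3p. A model that assigned construct libraries to a control pair from their own profiles was also run after seeing the data and dropped, since the labels give no such assignment and its groups came from the measured values.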

Results

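Mature miRNAs were measured by small RNA sequencing in 10 libraries of SUM159PT cells. The constructs carried part of the 3'UTR of TRAF6, ABCA1 or HADHB, each a candidate trigger of target-directed miRNA degradation, in which extended pairing with a target RNA leads to loss of the miRNA. The labelled substrate is miR-146 for TRAF6 and miR-33 for ABCA1 and HADHB, and the series asks whether a construct lowers its substrate. TRAF6 relays receptor signals to NF-kappaB, ABCA1 exports cholesterol from cells, and HADHB is a subunit of the mitochondrial enzyme of fatty acid oxidation. There were 2 libraries per construct and 4 libraries with a scrambled control. Depth was 3969252 and 4443406 miRNA reads for TRAF6, 3658005 and 5369054 for ABCA1, 4278402 and 4440670 for HADHB, and 4271983, 4204702, 3534573 and 4560500 for control replicates 1 to 4. Between 805 and 880 miRNAs were detected per library, and the 3 most abundant took 32% to 35.2% of the reads. In the controls, miR-92a-3p of the growth-promoting MIR17HG cluster took 12.6% of the reads, miR-22-3p 10.7%, let-7a-5p 10.5%, miR-100-5p 7.01% and miR-21-5p 4.46% (means, n = 4). None of these 5 passed the test with any construct, with log2 fold changes from -1.17 to 0.53 and the adjusted p of miR-100-5p with HADHB, 0.178, as the smallest.

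The 4 control libraries formed 2 pairs. Between replicates 1 and 2 and replicates 3 and 4, limma called 158 of 386 miRNAs, 84 higher and 74 lower in replicates 1 and 2, in a model with the pairs as separate groups that was chosen after seeing the data. The position of each library along this difference was taken as the median over 44 of these miRNAs, with 0 at the mean of control replicates 3 and 4 and 1 at the mean of replicates 1 and 2. TRAF6 libraries lay at 0.89 and 0.86, HADHB libraries at 0.40 and 0.32, and ABCA1 libraries at 0.03 and 0.05. The first principal component held 36.9% of the variance. Values of the miR-33 and miR-146 guides against each control pair are therefore given beside those against all 4 controls.

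**Figure D1:**
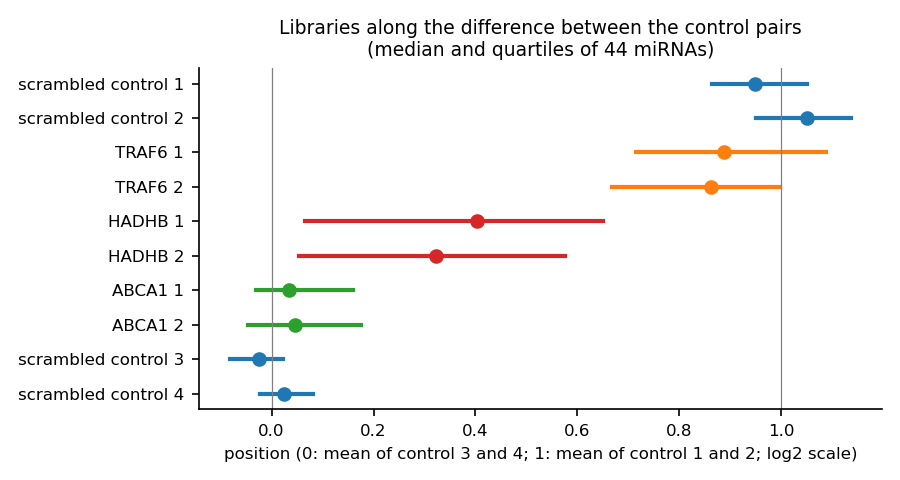
Position of each of the 10 libraries along the difference between the control pairs (x axis, log2 scale; 0 is the mean of control replicates 3 and 4 and 1 the mean of replicates 1 and 2), as the median (point) and quartiles (line) of 44 miRNAs. TRAF6 libraries lie at 0.89 and 0.86, HADHB libraries at 0.40 and 0.32, and ABCA1 libraries at 0.03 and 0.05.

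With the TRAF6 construct, miR-146b-5p, a repressor of TRAF6 and IRAK1 in NF-kappaB signalling, was measured at 24.8 ± 12.7 RPM (SD, n = 2) against 81.0 ± 16.9 RPM (n = 4) in the controls. This is a level 3.34-fold lower, with a log2 fold change of -1.74 ± 0.38 (SE) that did not pass over all miRNAs (limma adjusted p = 0.649) and passed adjusted over the list alone (adjusted p = 0.0074 over the 4 guides). Its close relative miR-146a-5p, which shares the seed, was measured at 464 ± 145 RPM (n = 2) against 795 ± 437 RPM (n = 4), a log2 fold change of -0.63 ± 0.51 (adjusted p = 0.649), or -0.95 without TRAF6 replicate 1, -0.31 without TRAF6 replicate 2 and -0.35 without control replicate 3. The miR-33 guides, which repress ABCA1 and other genes of cholesterol export, had log2 fold changes of -0.17 for miR-33a-5p and -0.25 for miR-33b-5p (both adjusted p = 0.649, the second -0.15 without control replicate 1). They were -0.25 and -0.49 against control replicates 1 and 2 and -0.10 and -0.0069 against replicates 3 and 4, and did not pass over all miRNAs. Adjusted over the list alone, miR-33b-5p did pass against control replicates 1 and 2, although it is not the labelled substrate of TRAF6. Both TRAF6 libraries, with 134 and 70 reads of miR-146b-5p, were below every control library. The exact permutation test gave p = 0.0667 for miR-146b-5p, the smallest that 15 splits allow, and p = 0.4 for miR-146a-5p. Over all miRNAs limma called 0 of 386, with 25 at an unadjusted p under 0.05, and edgeR called 0, also with 25.

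The result depended on the control pair. Against control replicates 3 and 4 alone, miR-146b-5p had a log2 fold change of -1.94 and miR-146a-5p one of -1.36 (adjusted p = 0.018 for both), among 136 calls. Against control replicates 1 and 2 alone, miR-146b-5p stayed at -1.54 (adjusted p = 0.413), miR-146a-5p turned to 0.10 and limma called 0 of 385, with 40 at an unadjusted p under 0.05. miR-146a-5p itself was at 424 ± 29.3 RPM in control replicates 1 and 2 and 1165 ± 148 RPM in replicates 3 and 4 (SD, n = 2 each). Without TRAF6 replicate 2 the model called 2 miRNAs. MIR146A lies on chromosome 5 from 160485352 to 160485450, over an exon of MIR3142HG, and MIR146B on chromosome 10 from 102436512 to 102436584, in no other gene (GRCh38).

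**Figure D2:**
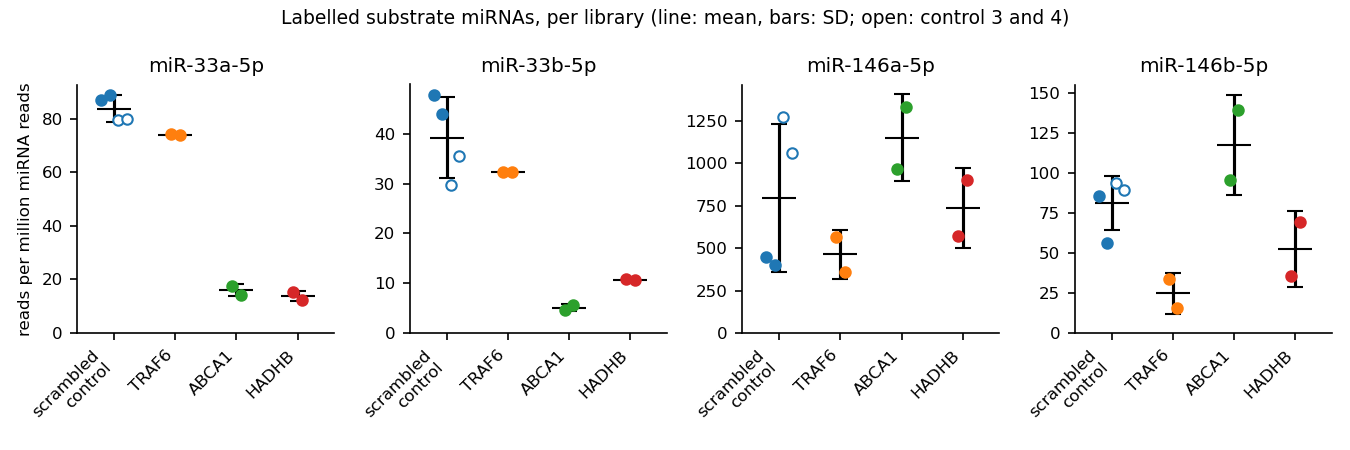
Levels of miR-33a-5p, miR-33b-5p, miR-146a-5p and miR-146b-5p (y axes, RPM, each from 0) in each library of the control and the 3 constructs, with the mean (line) and SD (bars); open circles are control replicates 3 and 4. The ABCA1 and HADHB libraries lie below every control and TRAF6 library for both miR-33 guides, and the TRAF6 libraries lie below every other library for miR-146b-5p. For that miRNA TRAF6 replicate 1 (33.8 RPM) lies only just below HADHB replicate 1 (35.5 RPM).

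In the same comparison no list passed by camera (0 of 13, 4 at an unadjusted p under 0.05, smallest adjusted p = 0.0588, and adjusted p = 0.331 as the smallest with an estimated correlation). No member passed over all miRNAs or adjusted over the list alone. fry called 1 list, the MIR17HG cluster and paralogs (adjusted p = 9.2e-04, median log2 -0.13 over 9 measured of 13), whose member miR-17-5p, a promoter of cell proliferation, had -0.30 ± 0.12. Among the families that restrain growth, let-7c-5p had a log2 fold change of -0.18 ± 0.13 (9 measured), miR-497-5p of the miR-16 family -0.33 ± 0.25 (6 measured) and miR-34c-5p of the p53-induced miR-34 family -1.11 ± 0.83 (3 measured). miR-29a-3p, which represses collagen genes, had -0.54 ± 0.30 (3 measured, and 0.012 without TRAF6 replicate 1), miR-30a-5p 0.22 ± 0.11 (5 measured) and miR-181b-5p 0.18 ± 0.07 (4 measured). miR-200b-3p, which maintains the epithelial state, had -0.66 ± 0.55, with 2 of 5 members measured. Of 4 measured inflammation-induced miRNAs, miR-21-5p had 0.10 ± 0.12. miR-26a-5p led the 7 measured ABCA1-targeting miRNAs with -0.23 ± 0.07. Among 8 measured miRNAs with endogenous triggers, miR-7-5p, which the long noncoding RNA Cyrano degrades, had 0.77 ± 0.44. miR-410-3p of the imprinted 14q32 cluster had -1.20 ± 0.47 (6 of 31 measured), miR-10a-5p of the mesenchymal list -1.30 ± 0.65 (10 measured) and miR-183-5p of the hypoxia and stress list -0.16 ± 0.08 (7 measured). Markers of other tissues were each represented by 1 measured miRNA: placental miR-512-3p had -0.01 ± 0.77, erythroid miR-486-5p, which was far lower in control replicate 1 than in the other controls, 1.73 ± 1.5 (0.32 without control replicate 1) and neuronal miR-138-5p 0.69 ± 0.53 (0.36 without control replicate 3 and 0.45 without control replicate 4). Leaving out 1 library moved several of these values by over 1.5 times: without TRAF6 replicate 1, miR-410-3p had -0.74, miR-10a-5p -0.72, miR-7-5p 0.47, miR-200b-3p -1.13 and miR-512-3p -0.56, and without TRAF6 replicate 2, miR-29a-3p had -1.10, miR-200b-3p -0.20 and miR-512-3p 0.54. Without control replicate 3 or 4, miR-497-5p had -0.19 and -0.22, miR-34c-5p -0.66 in both, miR-21-5p 0.047 and 0.049 (0.17 without control replicate 2) and miR-512-3p -0.39 and -0.37, and without control replicate 3, miR-200b-3p had -0.30 and miR-7-5p 0.49. Median, mean and test differed in sign for the miR-30, inflammation, endogenous-trigger and mesenchymal lists.

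Set against the other constructs, which carry sites for another substrate, the TRAF6 libraries again had the lowest miR-146b-5p. TRAF6 replicate 1 (33.8 RPM, 134 reads) was only just below HADHB replicate 1 (35.5 RPM, 152 reads). Their 95% counting intervals overlapped (28.3 to 40.0 and 30.1 to 41.6 RPM). The ABCA1 libraries held 117 ± 30.9 RPM and the HADHB libraries 52.3 ± 23.8 RPM (SD, n = 2 each), and the log2 fold change of TRAF6 against both was -1.67 ± 0.38 (adjusted p = 0.097, and 0.0032 adjusted over the list alone). miR-146a-5p stood at 1151 ± 258 RPM with ABCA1 and 737 ± 235 RPM with HADHB (n = 2 each), a log2 fold change of -0.99 ± 0.51 (adjusted p = 0.275). It also differed between the control pairs, at 424 RPM in replicates 1 and 2 and 1165 RPM in replicates 3 and 4. Along that difference the TRAF6 libraries lay near replicates 1 and 2, and the ABCA1 and HADHB libraries farther off. For miR-146a-5p and for the counts of calls, this contrast therefore cannot separate the construct from that difference. limma called 3 of 386 miRNAs in this comparison, all higher with TRAF6: miR-33a-5p (2.25 ± 0.13), miR-33b-5p (1.98 ± 0.20) and miR-501-3p, the last named after its values were seen (0.95 ± 0.13, adjusted p = 0.011, but 0.107 without TRAF6 replicate 2, 0.055 without ABCA1 replicate 1 and 0.243 without TRAF6 replicate 1, ABCA1 replicate 1 and control replicate 3 together). edgeR also called 3. The level of miR-501-3p was 196 ± 24.9 RPM with TRAF6, 139 ± 1.10 RPM with ABCA1 and 73.2 ± 5.82 RPM with HADHB (SD, n = 2 each). Its difference was thus larger against HADHB than against ABCA1. The calls were 107 (50 higher, 57 lower) with control replicates 1 and 2 alone in the model, 121 (53 and 68) with replicates 3 and 4 alone, 122 (59 and 63) with the pairs as 2 groups and 110 (50 and 60) with no controls, and 6 without ABCA1 replicate 2 and 5 without HADHB replicate 2. With only 1 control pair in the model the same contrast of miR-146b-5p had an adjusted p of 0.029 with replicates 1 and 2 and 0.019 with replicates 3 and 4.

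With the ABCA1 construct, both miR-33 guides fell. miR-33a-5p, which is encoded in an intron of SREBF2, the activator of cholesterol synthesis, went from 83.8 ± 4.89 RPM (SD, n = 4) in the controls to 15.9 ± 2.23 RPM (n = 2), a level 5.03-fold lower. miR-33b-5p, from an intron of the lipid synthesis regulator SREBF1, went from 39.2 ± 8.16 RPM (n = 4) to 5.12 ± 0.665 RPM (n = 2), 6.49-fold lower. Both folds come from the model on log2(RPM + 1) and are smaller than the ratios of the mean RPM values. Their log2 fold changes were -2.33 ± 0.13 (SE, adjusted p = 3.5e-05) and -2.70 ± 0.20 (adjusted p = 1.5e-04), and both also passed adjusted over the list alone (adjusted p = 3.7e-07 and 1.6e-06). The miR-146 guides had log2 fold changes of 0.70 for miR-146a-5p and 0.53 for miR-146b-5p and did not pass (both adjusted p = 0.592). Against control replicates 1 and 2 alone miR-146a-5p passed at 1.42 (adjusted p = 0.015), while against replicates 3 and 4 alone it had -0.030 (adjusted p = 0.998), and miR-146b-5p had 0.73 and 0.33. Without control replicate 2 miR-146a-5p had 0.43, and miR-146b-5p had 0.80 without ABCA1 replicate 1 and 0.26 without ABCA1 replicate 2. miR-33a-5p and miR-33b-5p were the only calls of limma among 386 miRNAs, with 24 at an unadjusted p under 0.05, and edgeR called 2.

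Against control replicates 1 and 2 the log2 fold changes were -2.40 for miR-33a-5p and -2.94 for miR-33b-5p, and against replicates 3 and 4 they were -2.26 and -2.46. The exact permutation test gave p = 0.0667 for each miRNA, the smallest that 15 splits allow. miR-33b-5p rested on 17 and 30 reads in the ABCA1 libraries and miR-33a-5p on 64 and 77. The hairpins lie on chromosome 22 from 41900944 to 41901012 for MIR33A and on chromosome 17 from 17813836 to 17813931 for MIR33B (GRCh38). The number of calls was 141 against control replicates 1 and 2 alone, 2 against replicates 3 and 4 alone, 1 with a filter of 50 RPM and 7 without ABCA1 replicate 2.

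By camera, 2 of 13 lists were higher with the ABCA1 construct. These were the growth-restraining let-7 family (median log2 0.28 over 9 members, adjusted p = 0.038) and the imprinted 14q32 cluster (median 0.95 over 6 members, adjusted p = 0.034), with an adjusted p of 0.657 for both with an estimated correlation. No member of either passed, over all miRNAs or adjusted over the list alone: let-7f-5p had 0.39 ± 0.22 and miR-410-3p 1.06 ± 0.47. Both lists also differed between the control pairs, along which the ABCA1 libraries lay next to control replicates 3 and 4, and no list passed against that pair alone. Without control replicate 1 or 2 no list passed, and 1 passed without ABCA1 replicate 1. In the remaining lists 0 members passed, over all miRNAs or adjusted over the list alone, and no camera adjusted p passed. Their members with the smallest p included miR-106b-5p (-0.17 ± 0.10), miR-16-5p, which represses cell cycle genes (0.20 ± 0.08), miR-34a-5p, induced by p53 (0.66 ± 0.42), miR-29b-3p, which the NREP RNA degrades (-0.99 ± 0.44, and 0.014 without ABCA1 replicate 1), and miR-30d-5p (0.15 ± 0.10). miR-181a-5p had 0.41 ± 0.19, miR-155-5p, induced in inflammation, 0.14 ± 0.06, miR-128-3p, reported to target ABCA1, -0.27 ± 0.15, miR-100-5p -0.69 ± 0.31 and miR-182-5p 0.30 ± 0.15. miR-200b-3p had 0.32 ± 0.55, and the tissue markers miR-512-3p, miR-486-5p and miR-138-5p had -1.36 ± 0.77, 1.69 ± 1.5 (0.28 without control replicate 1) and -0.86 ± 0.53 (-0.56 without control replicate 2). fry called the inflammation list (adjusted p = 0.033, median 0.16), which camera did not call (adjusted p = 0.311, and adjusted p = 0.657 with an estimated correlation). Leaving out 1 library moved several of these values by over 1.5 times: without control replicate 2, let-7f-5p had 0.20, miR-34a-5p 0.38 and miR-200b-3p 0.038, and without control replicate 1, miR-182-5p had 0.19 and miR-200b-3p 0.11. Without ABCA1 replicate 1, miR-128-3p had -0.43 and miR-200b-3p 0.50, and without ABCA1 replicate 2 they had -0.11 and 0.15 and miR-29b-3p -2.00, while miR-200b-3p had 0.68 without control replicate 3. Median, mean and test differed in sign for the MIR17HG and miR-30 lists.

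With the HADHB construct, miR-33a-5p and miR-33b-5p fell, and so did miR-501-3p, a miRNA of the CLCN5 intron cluster on the X chromosome. miR-33a-5p was at 13.8 ± 1.98 RPM (SD, n = 2), 5.76-fold lower than in the controls (log2 -2.52 ± 0.13, adjusted p = 1.9e-05). miR-33b-5p was at 10.7 ± 0.119 RPM (n = 2), 3.39-fold lower (log2 -1.76 ± 0.20, adjusted p = 0.0026). miR-501-3p was at 73.2 ± 5.82 RPM (n = 2) against 165 ± 19.2 RPM (n = 4), a log2 fold change of -1.16 ± 0.13 (adjusted p = 0.0026). The miR-146 guides had log2 fold changes of 0.03 for miR-146a-5p (adjusted p = 0.987) and -0.67 for miR-146b-5p (adjusted p = 0.514). Against control replicates 1 and 2 alone they had 0.76 and -0.47, and against replicates 3 and 4 alone -0.69 and -0.87, none of which passed over all miRNAs. miR-146a-5p ran from -0.30 without HADHB replicate 2 to 0.36 without HADHB replicate 1 and was also negative without control replicate 1 or 2, and miR-146b-5p had -0.20 without HADHB replicate 1 and -1.14 without HADHB replicate 2. limma called miR-33a-5p, miR-33b-5p and miR-501-3p, 3 of 386 miRNAs and all lower, with 49 at an unadjusted p under 0.05, and edgeR called 3. All 3 were lower in both HADHB libraries than in every control library, and the miR-33 guides also passed adjusted over the list alone (adjusted p = 2.0e-07 and 3.9e-05).

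Against control replicates 1 and 2 the log2 fold changes were -2.60 for miR-33a-5p, -2.01 for miR-33b-5p and -1.26 for miR-501-3p. Against replicates 3 and 4 they were -2.45, -1.52 and -1.05. The exact permutation test gave p = 0.0667 for each miR-33 guide, the smallest that 15 splits allow, and the reads behind them were 65 and 55 for miR-33a-5p and 46 and 47 for miR-33b-5p. MIR501 lies on chromosome X from 50009722 to 50009805. The free text of the titles of these libraries names the ABCA1 3'UTR, so their identity rests on the sample names. The number of calls was 77 against control replicates 1 and 2 alone, 81 against replicates 3 and 4 alone and 7 without HADHB replicate 2, and miR-501-3p did not pass without TRAF6 replicate 1, ABCA1 replicate 1 and control replicate 3 together (-1.18, adjusted p = 0.074).

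Tested against each control pair separately, 8 miRNAs were lower and 5 higher with HADHB against both. Of 380 miRNAs tested against both pairs, 13 passed in both in the same direction and 10 passed in opposite directions. Independent lists of those sizes would share 3.99 lower, 4.11 higher and 8.10 in opposite directions, so the higher miRNAs were not shown beyond chance. Simulated sets with no difference between any groups gave 0 in both (50 sets, highest 0), but they hold no difference between the control pairs, and both comparisons share the HADHB libraries, so neither number sets a level for the lower miRNAs. Apart from miR-33a-5p, miR-33b-5p and miR-501-3p, the lower miRNAs were miR-502-3p (log2 -0.89 against control replicates 1 and 2 and -0.71 against replicates 3 and 4), miR-99b-5p (-1.11 and -0.70), miR-100-5p (-1.64 and -0.69), miR-224-5p (-0.91 and -0.28) and miR-96-5p (-0.48 and -0.80). These miRNAs were chosen after their values were seen, and none but miR-33a-5p, miR-33b-5p and miR-501-3p passed against all 4 controls. miR-502-3p lies beside miR-501 in CLCN5, and miR-100-5p comes from MIR100HG, a host gene tied to mesenchymal traits. A shared effect at the CLCN5 site was not tested, and miR-501-5p, from the hairpin of miR-501-3p, had 0.044 and -0.17. miR-100-5p was at 29630 ± 2480 RPM with HADHB (SD, n = 2), 92486 ± 6203 RPM in control replicates 1 and 2 and 47787 ± 2554 RPM in replicates 3 and 4 (n = 2 each). The higher miRNAs were miR-127-3p of the 14q32 cluster (4.40 and 0.55), miR-3176 (2.04 and 0.61), miR-210-3p (0.40 and 0.42), miR-671-3p (0.24 and 0.38) and miR-155-5p (0.20 and 0.20). miR-127-3p was at 9.83 RPM in control replicate 1 and at 0 in control replicate 2, so that its 4.40 depends on the pseudocount, and against all controls its log2 fold change was 2.48, or 1.26 without control replicate 2. With ABCA1, 2 miRNAs passed against both pairs, miR-33a-5p and miR-33b-5p, and with TRAF6 limma called 0 in both (0 of 385 against replicates 1 and 2, 40 of them at an unadjusted p under 0.05, and edgeR was not run on the pairs).

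**Figure D3:**
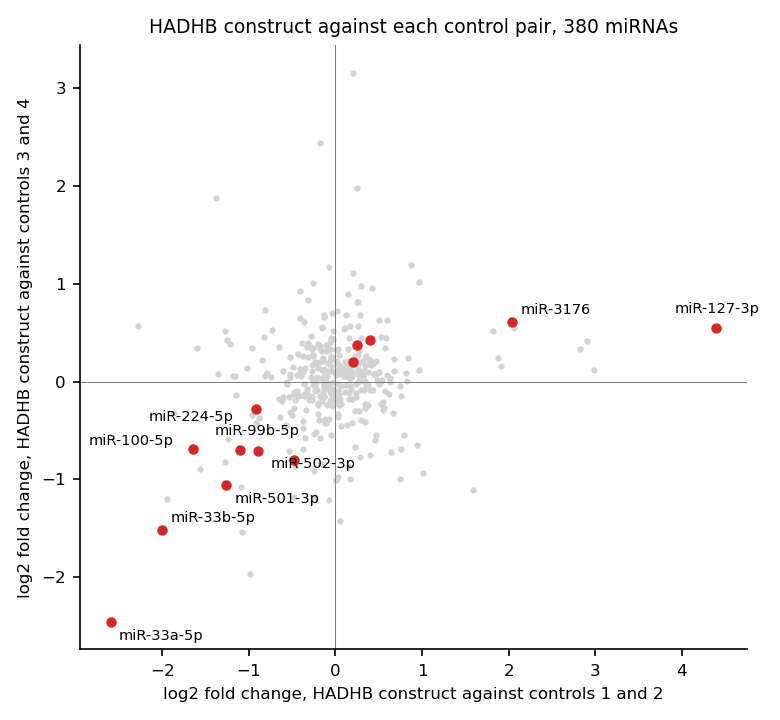
Log2 fold change of 380 miRNAs with the HADHB construct against control replicates 1 and 2 (x axis) and against control replicates 3 and 4 (y axis), with the 13 miRNAs that passed in the same direction against both in red. miR-33a-5p and miR-33b-5p lie farthest to the lower left, at -2.60 and -2.45 and at -2.01 and -1.52.

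The same 2 lists were higher by camera with HADHB: let-7 (median log2 0.26 over 9 members, adjusted p = 0.017) and 14q32 (median 1.24 over 6 members, adjusted p = 0.0071). With an estimated correlation the adjusted p was 0.962 for both, and 0 of their members passed, over all miRNAs or adjusted over the list alone. Both differed between the control pairs, between which the HADHB libraries lay. Against control replicates 3 and 4 alone neither passed (adjusted p = 0.809 and 0.196), while the miR-34 family list did (adjusted p = 0.0246). Its members were lower there: miR-34a-5p had -0.54, miR-34c-5p -1.10 and miR-449a -0.75. Against control replicates 1 and 2 alone this list passed as well (camera adjusted p = 0.0203), but its members were higher (0.79, 1.59 and 0.40). Without control replicate 2 no list passed, and 1 passed without control replicate 1 or without HADHB replicate 1. let-7b-5p had 0.29 ± 0.10 and miR-409-3p 1.31 ± 0.52. In other lists, no member passed over all miRNAs and 3 passed adjusted over the list alone: miR-155-5p of the inflammation list (0.20 ± 0.06, 1 of 4 members) and miR-210-3p, the main hypoxia-induced miRNA, and miR-96-5p of the hypoxia and stress list (0.41 ± 0.08 and -0.64 ± 0.16, 2 of 7 members). These lists did not pass by camera (adjusted p = 0.885 and 0.990, and 0.962 and 0.990 with an estimated correlation). The remaining members with the smallest p were miR-19b-3p (-0.26 ± 0.10), miR-200c-3p (0.69 ± 0.44, but 0.012 without HADHB replicate 2 and 1.37 without HADHB replicate 1 and 0.45 without control replicate 3), miR-16-5p (0.17 ± 0.08), miR-449a (-0.17 ± 0.46, from -0.49 without control replicate 2 to 0.12 without control replicate 3), miR-29c-3p (-0.27 ± 0.16), miR-30b-5p (-0.16 ± 0.06) and miR-181b-5p (0.17 ± 0.07). miR-145-5p, a smooth muscle miRNA reported to target ABCA1, had -0.51 ± 0.22, miR-335-3p -0.25 ± 0.10 and miR-100-5p -1.17 ± 0.31. The tissue markers miR-512-3p, miR-486-5p and miR-138-5p had -1.52 ± 0.77, 1.66 ± 1.5 (0.26 without control replicate 1) and -0.41 ± 0.53 (-0.16, -0.11, -0.74 and -0.65 without control replicates 1 to 4). Median, mean and test differed in sign for the MIR17HG, miR-16 and miR-181 lists.

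Pooled over both constructs labelled with miR-33, miR-33a-5p fell by 2.43 on the log2 scale (SE 0.11, adjusted p = 5.2e-06) and miR-33b-5p by 2.23 (SE 0.16, adjusted p = 1.4e-04), in 4 of 4 libraries below every control library. Against control replicates 1 and 2 alone their log2 fold changes were -2.50 and -2.47, and against replicates 3 and 4 alone -2.36 and -1.99. The exact permutation test gave p = 0.0286 for each, the smallest that 70 splits allow. It takes the libraries as exchangeable, although the controls formed pairs and the other libraries came from both constructs. Measured against the TRAF6 construct in place of the scrambled control, miR-33a-5p had a log2 fold change of -2.25 ± 0.13 (adjusted p = 4.6e-05) and miR-33b-5p one of -1.98 ± 0.20 (adjusted p = 0.0016). miR-501-3p was the only other call of limma in the pooled comparison (-0.70 ± 0.11, adjusted p = 0.022, 3 of 386 called, 37 at an unadjusted p under 0.05), and edgeR called 3. With ABCA1 alone miR-501-3p had -0.24 ± 0.13 (limma adjusted p = 0.592) and with HADHB alone -1.16 ± 0.13, so the pooled call came mainly from the HADHB libraries. let-7 (median log2 0.26, adjusted p = 0.0032) and 14q32 (median 1.10, adjusted p = 0.0017) were higher by camera, with an adjusted p of 0.690 for both with an estimated correlation and 0 members passing over all miRNAs or adjusted over the list alone. Against control replicates 3 and 4 alone neither passed (adjusted p = 0.946 and 0.250). miR-155-5p (0.17), miR-210-3p (0.26) and miR-96-5p (-0.43) passed adjusted over the list alone only, and their lists did not pass by camera (adjusted p = 0.422 and 0.803, and 0.690 and 0.918 with an estimated correlation), while fry called 1 list, the inflammation list (adjusted p = 0.037, median 0.12). Signs of median, mean and test differed for the MIR17HG and the hypoxia and stress lists. The number of calls was 138 against control replicates 1 and 2 alone and 29 against replicates 3 and 4 alone, and 1 list in place of 2 passed without control replicate 2. Without ABCA1 replicate 2 it was 5, and the adjusted p of miR-501-3p ran from 0.0584 to 0.124 without control replicate 1, control replicate 3 or any 1 of the ABCA1 and HADHB libraries. It was 0.065 with no filter, 0.0584 with a term for the number before cells, and 0.523 without TRAF6 replicate 1, ABCA1 replicate 1 and control replicate 3 together, where miR-33b-5p against TRAF6 had 0.059.

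Between the constructs that share the label miR-33, the guides differed in pattern. miR-33b-5p was higher with HADHB than with ABCA1, with a log2 difference of 0.94 ± 0.23 (SE, n = 2 each) that did not pass over all miRNAs (limma adjusted p = 0.287) and passed adjusted over the list alone (adjusted p = 0.0135). miR-33a-5p differed by -0.19 ± 0.15 (adjusted p = 0.635), or -0.059 and -0.33 without ABCA1 replicate 1 or 2 and -0.33 and -0.057 without HADHB replicate 1 or 2. The reads of miR-33b-5p per read of miR-33a-5p were 0.708 and 0.855 with HADHB, 0.266 and 0.390 with ABCA1, 0.434 and 0.439 with TRAF6, and 0.374 to 0.548 in the controls. limma called 0 of 386 miRNAs, with 38 at an unadjusted p under 0.05, and edgeR called 1, miR-501-3p (limma log2 -0.92 ± 0.15, adjusted p = 0.110). No list passed by camera (0 of 13, 0 at an unadjusted p under 0.05, smallest adjusted p = 0.898, and 0.903 with an estimated correlation), and no member passed adjusted over the list alone. Signs of median, mean and test differed for the miR-29, inflammation, ABCA1-targeting and mesenchymal lists. With only 1 control pair in the model, which does not enter this contrast but sets its spread, miR-33b-5p passed over all miRNAs (adjusted p = 0.0133 with replicates 1 and 2 and 0.0140 with replicates 3 and 4). The calls were then 35 and 58, and they were 4 without ABCA1 replicate 2 and 2 without HADHB replicate 2.

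Arm ratios compare the guide with the passenger of the same hairpin, since degradation by a target acts on the loaded guide. For miR-146b the log2 ratio of 5p to 3p was lower with TRAF6 than in the controls by a log2 difference of -1.45 ± 0.67, which did not pass (limma adjusted p = 0.727). The exact permutation test gave p = 0.0667, the smallest possible. The difference rested on TRAF6 replicate 2, with a log2 ratio of 1.80, since TRAF6 replicate 1 (3.65) lay next to control replicate 2 (3.72), and it was -0.52 without TRAF6 replicate 2 and -2.38 without TRAF6 replicate 1. miR-146b-3p was measured at only 2.79 ± 1.46 RPM with TRAF6 (SD, n = 2) and 3.55 ± 1.03 RPM in the controls (n = 4). Of 92 hairpins, 0 passed with TRAF6 (limma, 4 at an unadjusted p under 0.05) and 0 with ABCA1 (9 at an unadjusted p under 0.05), and edgeR was not run on ratios. With HADHB 2 passed: miR-99b (-1.43 ± 0.19) and miR-100 (-1.02 ± 0.13), each with an adjusted p of 0.0035 and each lower in the 5p arm relative to the 3p arm. Their 5p arms share a seed with miR-99a-5p, which was at 68.0 RPM in HADHB replicate 1 and 236 RPM in HADHB replicate 2. It was at 271 ± 13.0 RPM in the controls (SD, n = 4) and 233 ± 6.64 RPM with ABCA1 (n = 2). The low mean of miR-99a-5p with HADHB thus rested on 1 library, and it did not pass against both control pairs. The hairpins of miR-99b and miR-100 are encoded on chromosomes 19 and 11. Both calls were lost with a term for the number after rep (-1.35 and -0.99, adjusted p = 0.081 for both) and without TRAF6 replicate 1, ABCA1 replicate 1 and control replicate 3 together (-1.39 for miR-99b, adjusted p = 0.067 for both it and miR-100). The count was 1 without TRAF6 replicate 2 for TRAF6, 1 without ABCA1 replicate 1 and 2 without ABCA1 replicate 2 for ABCA1, and 4 without HADHB replicate 2 for HADHB.

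**Figure D4:**
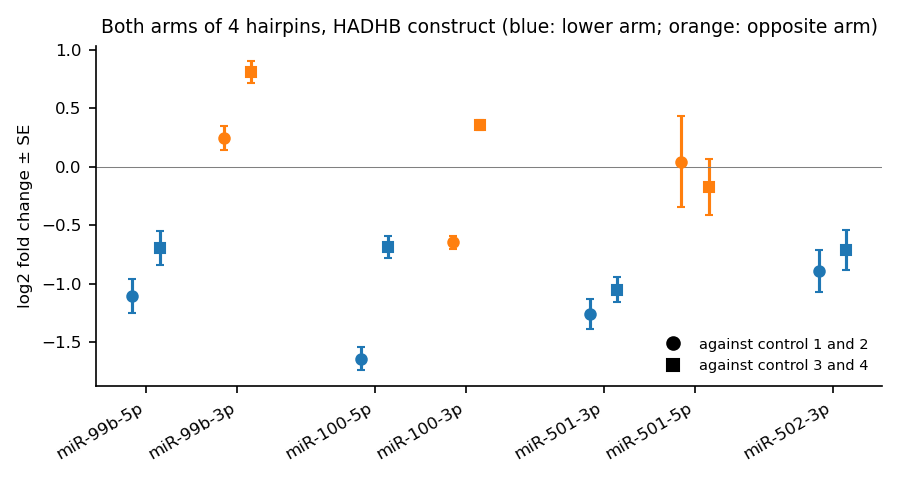
Log2 fold changes with SE (y axis) of both arms of miR-99b, miR-100 and miR-501 and of miR-502-3p, HADHB construct against control replicates 1 and 2 (circles) and against control replicates 3 and 4 (squares). The lower arms (blue) lie below 0 against both pairs, while the opposite arms (orange) lie on both sides of 0.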

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

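The tests of hairpin output and of counting noise were chosen only after the result was seen, while the search for a gaining miRNA was set out before its result was known.

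In 3 of 57 sets of control values, 1 library lay far from the other 3, above the 95% critical value of Dixon's test. The measure was the gap of that library to the nearest one, divided by the range of all 4, both on log2(RPM + 1). These gaps differ from gaps between the RPM values given below, on which the test was not run. The 3 marks therefore hold for the log2 scale only. Chance alone marks about 1 in 20 groups. miR-486-5p, an erythroid miRNA, was at 14.7 RPM in control replicate 1 and at 780 ± 152 RPM (SD, n = 3) in the others, a gap of 0.916 of the range. miR-200c-3p was at 1.98 RPM in control replicate 3 against 4.84 ± 0.342 RPM (n = 3), a gap of 0.856. miR-183-5p was at 1006 RPM in control replicate 4 against 1125 ± 11.3 RPM (n = 3), a gap of 0.836. The change of miR-33b-5p differed between the HADHB and ABCA1 constructs by 0.94 on the log2 scale (SE 0.23, limma adjusted p = 0.287 over all miRNAs and 0.0135 adjusted over the list alone), and it was higher in both HADHB libraries than in both ABCA1 libraries.

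The low value of miR-486-5p was 1 of 23 cases, over 15 miRNAs and 9 libraries, in which a miRNA in 1 library was at least 4-fold below the other library of its replicate pair, itself at 20 RPM or more; ABCA1 replicate 1 held 7 of them, and miR-125a-5p and miR-125b-5p were low in 4 libraries each. For miR-125a in HADHB replicate 2, 2 of the cases, both arms were low (-2.56 for 5p and -2.84 for 3p), so less output of the whole hairpin stays a candidate explanation there; for the 12 other cases with both arms tested it was argued against as the whole cause, since the opposite arm had a median log2 difference of 0.035 (from -1.40 to 1.34, 2 of them below -0.5) where the low arm had a median of -4.67, and it stays open where no opposite arm was tested. Counting noise alone, with reads drawn at equal shares in both libraries, would give 5.7e-09 such cases over the 386 miRNAs and 5 replicate pairs searched. The rule for a case almost fixed this outcome, since counting rarely gives a 4-fold drop from 20 RPM or more at these depths. The number thus says only that drops of this size exceed counting error. Reads given to another listed miRNA stay open: 12 of the 23 cases had a miRNA that gained enough, which met the level set for this cause, but the same search in unrelated replicate pairs gives 15.1, so the test does not separate it from chance, and 11 cases, every miR-125a-5p and miR-28-3p case among them, had none. Reads lost outside the listed miRNAs were not tested, and no biological explanation was tested, since the design gives no difference within a replicate pair.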

How the results depend on the processing

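The tests chosen only after the result was seen were the model with the control pairs as 2 groups, the contrast between the pairs and the omission of the 3 libraries with low miR-125a-5p and miR-28-3p. miR-33a-5p kept its direction and its call in all 25 alternatives with ABCA1, with HADHB, pooled and against TRAF6, and miR-33b-5p in all 24 that tested it, except against TRAF6 without those 3 libraries (-1.93, adjusted p = 0.059). Adjusted p-values reached at most 0.0149 for both with ABCA1, 0.0043 for miR-33a-5p with HADHB and 0.042 for miR-33b-5p with HADHB. miR-501-3p with HADHB kept its call in 24 of 25 alternatives and lost it without the 3 libraries (-1.18, adjusted p = 0.074). Pooled it lost its call in 9 of 25 (adjusted p from 0.0584 to 0.523): no filter, the term for the number before cells, the 3 libraries, and control replicate 1, control replicate 3 or any 1 ABCA1 or HADHB library left out. Except where stated the cause was not tested. A filter of 50 RPM tests fewer miRNAs and gave no value for miR-33b-5p or the miR-146b arm ratio.

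With control replicates 1 and 2 alone, the calls were 141 for ABCA1, 77 for HADHB, 138 pooled, 35 for HADHB against ABCA1 and 107 for TRAF6 against the other constructs, against 2, 3, 3, 0 and 3 with all controls. miR-146a-5p passed with ABCA1 (1.42, adjusted p = 0.015). miR-146a-5p with TRAF6 turned to 0.10, and against the other constructs miR-146a-5p (-0.99, adjusted p = 0.036) and miR-146b-5p (-1.67, adjusted p = 0.029) passed. Lists past the threshold were 4 for TRAF6, 4 for ABCA1, 4 pooled and 1 for HADHB against ABCA1, and 4 arm ratios passed for HADHB. Single miRNAs that turned were, with TRAF6, miR-200b-3p (0.081), miR-497-5p (0.047), miR-34c-5p (0.24), miR-21-5p (-0.060) and miR-138-5p (-0.15), and, with HADHB, miR-449a (0.40). The term for the number after rep, which leaves control replicates 3 and 4 without partners, gave these 6 values and the 0.10 of miR-146a-5p again by construction, with 124, 70, 113, 20 and 93 calls in the same order of comparisons, 4 lists for TRAF6, 1 list for HADHB against ABCA1 and 0 arm ratios for HADHB by limma (2 without the term; miR-99b -1.35 and miR-100 -0.99, adjusted p = 0.081 for both).

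With control replicates 3 and 4 alone, the calls were 136 for TRAF6, 81 for HADHB, 29 pooled, 58 for HADHB against ABCA1 and 121 for TRAF6 against the other constructs. miR-146a-5p turned with ABCA1 (-0.030) and with HADHB (-0.69). miR-146a-5p (-1.36) and miR-146b-5p (-1.94) passed with TRAF6, and against the other constructs they passed at -0.99 (adjusted p = 0.033) and -1.67 (adjusted p = 0.019). Lists past the threshold were 5 for TRAF6, 0 for ABCA1, 1 for HADHB (the miR-34 family, with its members lower), 0 pooled and 1 for HADHB against ABCA1. miR-200b-3p (-0.42) and miR-34a-5p (-0.0073) turned with ABCA1 and miR-138-5p (0.43) with HADHB. With the pairs as 2 groups, which takes their difference out of the spread, the calls were 49 for TRAF6, 63 for ABCA1, 58 for HADHB, 56 pooled, 56 for HADHB against ABCA1 and 122 for TRAF6 against the other constructs. miR-146b-5p then passed with TRAF6 (-1.74, adjusted p = 0.031, in a range of 0.018 to 0.898 over its alternatives) and against the other constructs (-1.67, adjusted p = 0.017), as did miR-146a-5p (-0.99, adjusted p = 0.024). None of these models takes the difference between the control pairs out of the contrast of TRAF6 with the other constructs. The calls of miR-146a-5p there cannot be told apart from it. The model with the pairs as 2 groups sets each construct against the mean of both pairs. A part of their difference thus stays in the contrasts with the controls as well. TRAF6 had 0 calls against replicates 1 and 2 alone, and ABCA1 had 2 against replicates 3 and 4 alone. Its 49 and 63 calls for TRAF6 and ABCA1 therefore cannot be told apart from the difference between the pairs. In this model, lists past the threshold were 2 for TRAF6, 4 for ABCA1 and 1 for HADHB against ABCA1.

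With only the compared groups in the model, 12 miRNAs passed for HADHB against ABCA1 and 110 for TRAF6 against the other constructs, miR-146b-5p passed against the other constructs (-1.67, adjusted p = 0.036), and 1 list passed for ABCA1 and 1 for HADHB against ABCA1. edgeR called 1 for HADHB against ABCA1, and miR-146a-5p with HADHB turned to -0.13. The filter of 50 RPM left 1 call for ABCA1, 0 lists for ABCA1 and HADHB, 1 list pooled, 2 lists between the control pairs and 5 arm ratios for HADHB. No filter gave 4 lists pooled and 7 between the control pairs. TMM gave 1 list for TRAF6, median-of-ratios 0 lists for ABCA1, and limma without the trend 1 list for ABCA1. With an estimated correlation 0 lists passed for ABCA1, HADHB, pooled and the control pairs. miR-512-3p with TRAF6 turned to 0.18 with a pseudocount of 0.1, 0.030 with TMM and 0.021 with median-of-ratios rescaling.

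Leaving out each library in turn, with a lone library assumed to vary like the other groups, gave 0 to 2 calls for TRAF6 (2 without TRAF6 replicate 2), 2 to 7 for ABCA1 (7 without ABCA1 replicate 2), 3 to 7 for HADHB (7 without HADHB replicate 2), 2 to 5 pooled (5 without ABCA1 replicate 2), 0 to 4 for HADHB against ABCA1 (4 without ABCA1 replicate 2 and 2 without HADHB replicate 2) 2 to 6 for TRAF6 against the other constructs (6 without ABCA1 replicate 2, 5 without HADHB replicate 2) and 101 to 154 between the control pairs (101 without control replicate 3). Lists ran from 0 to 4 for TRAF6 (1 without TRAF6 replicate 2, control replicate 3 or control replicate 4, 3 without control replicate 1, 4 without control replicate 2), 0 to 2 for ABCA1 (0 without control replicate 1 or 2, 1 without ABCA1 replicate 1), 0 to 2 for HADHB (0 without control replicate 2, 1 without control replicate 1 or HADHB replicate 1) and 1 to 3 pooled (1 without control replicate 2). Arm ratios ran from 0 to 1 for TRAF6 (1 without TRAF6 replicate 2), 0 to 2 for ABCA1 (1 without ABCA1 replicate 1, 2 without ABCA1 replicate 2) and 2 to 4 for HADHB (4 without HADHB replicate 2). miR-29a-3p with TRAF6 ran from -1.10 to 0.012 (0.012 without TRAF6 replicate 1), miR-512-3p with TRAF6 from -0.56 to 0.54 (0.54 without TRAF6 replicate 2), miR-29b-3p with ABCA1 from -2.00 to 0.014 (0.014 without ABCA1 replicate 1), miR-146a-5p with HADHB from -0.30 (without HADHB replicate 2) to 0.36 (without HADHB replicate 1) and miR-449a with HADHB from -0.49 to 0.12 (0.12 without control replicate 3). Without the 3 libraries with low miR-125a-5p and miR-28-3p the calls were 0 for TRAF6 by limma, 2 for ABCA1, 2 for HADHB, 2 pooled, 0 for HADHB against ABCA1, 1 for TRAF6 against the other constructs and 70 between the control pairs, 1 list passed for ABCA1, arm ratios were 1 for ABCA1 and 0 for HADHB (miR-99b -1.39, adjusted p = 0.067 for both it and miR-100), and miR-29b-3p with ABCA1 (0.013) and miR-449a with HADHB (0.12) turned. Depth sets a floor, since a value carried by 3 reads equals 0.559 to 0.849 RPM.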

Other observations

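The tests of scaling in the control pairs and of the HADHB miRNAs were chosen only after the result was seen, while those of unequal depth and of other splits were set out before their results were known. In control replicates 1 and 2 the growth-restraining let-7 family was lower than in replicates 3 and 4: 8 of 9 measured members were lower past the threshold, over all miRNAs and adjusted over the list alone (camera adjusted p = 8.0e-04, and adjusted p = 0.245 with an estimated correlation), with log2 differences of -0.83 ± 0.06 (SE) for miR-98-5p, -0.66 ± 0.08 for let-7d-5p and -0.33 ± 0.07 for let-7c-5p. All 6 measured members of the imprinted 14q32 cluster were lower by both adjustments (adjusted p = 0.0016, and 0.145 with an estimated correlation), among them miR-381-3p (-1.64 ± 0.18), miR-136-3p (-2.49 ± 0.37) and miR-411-5p (-1.75 ± 0.28). All 3 measured members of the p53-induced miR-34 family were lower by both adjustments (adjusted p = 0.0057, and 0.145 with an estimated correlation): miR-34c-5p (-2.69 ± 0.08), miR-34a-5p (-1.33 ± 0.13) and miR-449a (-1.14 ± 0.35), the last with an adjusted p of 0.185 without control replicate 2, 0.188 without control replicate 3 and 0.0557 to 0.0570 without any 1 of the ABCA1 and HADHB libraries. Without TRAF6 replicate 1, ABCA1 replicate 1 and control replicate 3 together, the calls between the pairs were 70, and let-7c-5p (adjusted p = 0.057), miR-411-5p (adjusted p = 0.051) and miR-449a (adjusted p = 0.238) did not pass. Of the mesenchymal and basal breast miRNAs, 5 of 10 measured were higher by both adjustments and none was lower (adjusted p = 0.024, and 0.163 with an estimated correlation), among them miR-222-3p (0.79 ± 0.06) and miR-221-3p (0.50 ± 0.04), which repress the cell cycle inhibitor CDKN1B, and miR-100-5p (0.95 ± 0.10). These 4 of 13 lists passed by camera, each with 2 libraries per side, and these miRNAs were chosen as the 3 with the smallest p in each list after the difference was seen.

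The annotated 3'UTRs of the 3 genes were searched for matches to bases 2 to 8 of the labelled substrates. ABCA1 held 4 matches to miR-33 in 3696 bases (exact Poisson p = 5.7e-05 from base composition) and HADHB 1 in 515 bases (exact Poisson p = 0.027). TRAF6 held 3 matches to miR-146 in 2811 bases (exact Poisson p = 0.0015) and 0 to miR-33. The constructs are labelled as holding a site for these miRNAs, so matches to the labelled substrates were to be found. These p-values only describe how rare such matches are for the base composition and do not test the labels. The part of each 3'UTR in the constructs is not given in the labels, so these are counts in the whole annotated 3'UTRs. For ABCA1 the 3696 bases are the sum over 3 annotated 3'UTRs, the longest of 3313 bases. A match in bases that they share would be counted more than once, so the 4 matches need not be separate sites.

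The difference between the control pairs, 158 calls, was weighed against 2 technical explanations. Scaling by a few abundant miRNAs was argued against by at least 151 calls under TMM or median-of-ratios rescaling. For unequal depth, every library was thinned to 3534573 reads, and 144 calls were left. The depths of replicates 1 and 2 (4271983 and 4204702 reads) lay between those of replicates 3 and 4 (3534573 and 4560500 reads). Depth thus did not divide the pairs, and thinning, which took few reads from each control library, was a weak test of it. A split of 8 libraries that set control replicates 1 and 2 with HADHB against control replicates 3 and 4 with ABCA1 called 93, which points to a structure of the samples, and the real split of controls against ABCA1 and HADHB called 2 in the same model, with 2 of the 35 splits, the real one included, at as many, so that chance cannot be excluded for that count of calls. Library or sequencing batch, culture and infection stay open, since the labels give none of them, and no biological explanation was tested.

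The 6 miRNAs other than miR-33 that were lower with HADHB against both control pairs were weighed in the same way, although with miR-33a-5p and miR-33b-5p they make 8 where independent lists would share 3.99 and simulated sets with no difference between any groups, the control pairs included, gave 0, so a part of them may be shared by chance. For miR-99b, miR-100 and miR-501, less output of the whole hairpin was tested through the opposite arms. These had a median log2 fold change of -0.064 (from -0.15 to 0.53) where the lower arms had -1.16. Each lay 1.02 to 1.43 above its lower arm. A gap is partly expected, since the lower arms were chosen for being low. Over all 92 hairpins the arm ratios of miR-99b and miR-100 passed with HADHB, and that of miR-501 did not. For miR-99b and miR-100 this argues against less output as the whole cause, within the limits given for these calls. For miR-501 it stays open, since the median is the value of miR-501-5p, whose SE was 0.32. Against control replicates 1 and 2 alone miR-100-3p was lower too (-0.65, limma adjusted p = 0.0011, beside -1.64 for miR-100-5p). Against replicates 3 and 4 it was higher (0.36, beside -0.69). A share of the fall of miR-100 against the first pair thus stays open. For miR-96, miR-224 and miR-502, 0 opposite arms could be tested, so less output of the whole hairpin stays open. Scaling by a few abundant miRNAs was argued against, since all 6 stayed lower and called against control replicates 3 and 4 under both rescalings. A biological explanation, pairing of the construct with these miRNAs, was tested through their seeds: the annotated 3'UTRs of HADHB and ABCA1 held 0 matches to bases 2 to 8 for miR-99b-5p, miR-100-5p, miR-224-5p, miR-501-3p and miR-502-3p, which argues against a match of that length there, and 1 for miR-96-5p (in ABCA1, exact Poisson p = 0.106), which does not decide. A shorter match of 6 seed bases was found for miR-224-5p (1 in ABCA1), so a shorter seed match stays open for it. Pairing without a seed match, an effect of the construct on arm choice or on trimming, and a difference between cultures remain untested.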
